A study of Mus musculus with 12 samples.

How the data were processed

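Per the labels, RNA from laser-captured tumour epithelium and stroma was labelled with Cy3 and a universal mouse reference RNA with Cy5 on every array, with no dye swap. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 as 2-colour scans. The deposited scanner files give the median intensity of each spot and of its local background in both channels, the intensity after Agilent's own background and dye correction, quality flags, and a log10 ratio of Cy5 over Cy3, per the file headers. The deposited value table holds log2 values whose making is not given in the sources used here. Set against the scanner ratios, its 6 epithelial columns ran as log2 of reference over sample of the same spot (r between -0.996 and -0.976 with sample over reference across spots, which are not independent replicates), centred near 0. Their medians were 0.02, 0.01 and 0.01 for KO replicates 1, 3 and 4 and 0.00, -0.01 and -0.05 for WT replicates 1, 2 and 3. Its 6 stromal columns had medians of 0.05, -0.01 and 0.00 for KO and 0.00, 0.01 and 0.01 for WT, and did not go with any array (r with their own array between -0.00834 for KO replicate 1 and 0.0054 for KO replicate 4, and at most 0.00738 in size with another array), so their row order, scale and direction stay unknown. They were not used.

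Each array has 62976 spots, of which 3671 are controls. The normexp method (offset 50) was applied to the median signals and local background, then loess within each array with control spots at weight 0, and the ratio was turned to sample over reference. The test had been planned on mean signals, but the median signals are what the files used here give. Spots flagged as non-uniform in either channel were set missing, and they numbered 211 on WT epithelium replicate 3 and at most 16 on the other arrays. Spots of a probe were averaged, giving 55681 probes. Of these 27235 were named by matching their accession, without version, to a RefSeq gene table of assembly GRCm38.p6, which gave 20660 genes. Since the headers name another build, no coordinates are given. A probe was kept where Cy3 was well above background on at least 3 of 12 arrays, and the brightest kept probe stood for a gene, which left 13275 genes, 2586 of them with over 1 kept probe.

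Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. KO and WT were compared within a compartment in a fit of the 4 group means over all 12 arrays (8 residual degrees of freedom). In its estimate of the spread this fit treats the 2 compartments of a tumour as independent. With tumour as a random block (estimated correlation 0.23) 829 genes passed in stroma in place of 859, and 1 in epithelium as before. Stroma and epithelium, and the difference of the KO effect between them, were tested with tumour as a fixed block (4 residual degrees of freedom). The pairing comes from the genotype and number in the titles of both compartments. Deviations from the group means correlated across genes between the compartments of a tumour at 0.09, 0.29 and 0.23 for KO tumours 1, 3 and 4 and at 0.45, 0.29 and 0.25 for WT tumours 1, 2 and 3, each above that of the epithelium with any other stroma of its group. Lists of genes, 25 in all, were tested with camera at a preset correlation of 0.01 over lists with at least 5 measured members, with the estimated correlation beside it. No list called at the preset value passed with an estimated correlation. The test fry, planned beside camera, asks whether the members of a list change, not whether they change more than other genes. At an adjusted p under 0.05 it called 0 lists in epithelium, 8 in stroma, 7 between compartments and 1 for the difference of the KO effect. Mean and camera direction differed in sign for 3 uncalled lists in epithelium and 2 in stroma, and mean and median for 4 and 1, and for 2 between compartments.

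Within each slide the KO arrays lie in the first row and the WT arrays in the second, so genotype and slide row cannot be told apart in the ratios, and the reference channel was tested in their place. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule takes Rarb and Wnt1 in every comparison. It adds the 10 largest rises and falls among called genes whose groups do not overlap or, between compartments, whose sign is the same in all 6 tumours. Where under 5 genes pass it adds the 10 smallest p among genes changed at least 2-fold, and it takes up to 4 called members of each list described, or the 2 with the smallest p where none was called. Symbols without a descriptive name were left out of the middle parts. A few genes that the rule takes are not described. Where a probe was not well above background on any array of a group, the fold is a bound from the Cy3 channel after loess and Aquantile, open to dye bias.

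In simulated data for the 13275 genes with the real spread, the test of KO against WT in epithelium recovered 30% of genes changed by 1 on the log2 scale, 88% at 2, 96% at 3 and 100% at 4, and in stroma 40%, 82%, 94% and 96%. For stroma against epithelium the shares were 80%, 98%, 100% and 100%, and for the difference of the KO effect 2%, 62%, 92% and 96%. Among 13055 unchanged genes 3, 8, 13 and 8 were called in the 4 tests. Other settings tried were Agilent's processed signals, no background subtraction, Aquantile, Cy3 alone, the deposited table in epithelium, other filters, the mean over probes, array weights, other blocks and each replicate left out.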

Results

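The series compared mammary tumours of mice that carry the MMTV-Wnt1 transgene, which drives the growth factor gene Wnt1 in mammary epithelium, between mice without a working Rarb gene (KO) and mice with the wild-type gene (WT). Rarb encodes the retinoic acid receptor beta, a nuclear receptor that regulates genes in response to retinoids. Epithelium and stroma of each tumour were separated by laser capture microdissection, in which cells are cut from a stained section under a microscope, and each RNA was hybridised to a 2-colour Agilent array against a common mouse reference RNA. The 12 arrays form 4 groups of 3, namely KO epithelium, WT epithelium, KO stroma and WT stroma, from 6 tumours that each gave both compartments. Cy3, the colour of the tumour sample, was well above background on 36.0% to 46.3% of probes per array, and no spot was saturated. The number of arrays limits the precision of every value. The labels do not state that each tumour came from a separate mouse, so p-values measure the spread between these samples.

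The targeted gene was looked at first. Positive values are tumour sample over reference. The scanner ratios and the 6 epithelial columns of the deposited table run the opposite way, reference over sample. The Rarb probe gave a log2 ratio of 0.24 ± 1.26 in KO epithelium and 0.29 ± 0.91 in WT epithelium, and of 1.497 ± 0.81 in KO stroma and 0.36 ± 0.89 in WT stroma (SD, n = 3 each). The differences between genotypes did not pass the test (limma adjusted p = 0.994 in epithelium and 0.402 in stroma), so Rarb mRNA did not separate the samples labelled KO from those labelled WT. Whether this probe lies in the deleted part of the gene is not given in the sources used here, and its values therefore check nothing about the labels. A second Rarb probe was not well above background on any array, WT included, and was left out by the filter. The Wnt1 transcript was high in both epithelia, at 7.26 ± 0.27 in KO and 7.35 ± 0.28 in WT (SD, n = 3 each), with no called difference (log2 fold change -0.09, SE 0.29, adjusted p = 0.959), and this small difference was positive under 6 of 21 other settings, among them without KO replicate 1 (0.0144) and without WT replicate 1 (0.0698). A second, dimmer Wnt1 probe gave -1.22 for the same comparison, with 0.96 to 1.44 on the KO and 1.77 to 3.28 on the WT arrays. Groups without overlap were seen for 14.1% of all genes, and this probe was not tested alone. The 2 probes thus leave open whether Wnt1 differed between the epithelia.

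The comparison of KO with WT epithelium asked which genes of the tumour cells differed with the genotype. A single gene passed the threshold. Tspan1, which encodes a tetraspanin membrane protein, was 7.37-fold higher in KO epithelium, with log2 ratios of 3.56 ± 0.42 in KO and 0.68 ± 0.27 in WT (SD, n = 3 each; log2 fold change 2.88, SE 0.31, limma adjusted p = 0.0321, and 0.00891 to 0.888 over the other settings). No gene was called lower, while 1070 of 13275 genes had an unadjusted p under 0.05. Among genes with the next smallest p and at least a 2-fold difference, none of which passed (adjusted p = 0.52 for each), the cytokine gene Il19 had a log2 fold change of 1.32, the sialyltransferase gene St8sia6 1.42, Pigz 1.22, the nuclear pore gene Nup37 1.08 and Mospd1 1.002. Negative values in this set were -1.08 for Sbk1, -1.06 for Ttc7b, -1.05 for the small heat shock protein gene Hspb9, and for Tcp10a at least 2.78-fold lower in KO, where its probe was not well above background on any array. The Tspan1 call was lost when any 1 of the 6 epithelial arrays was left out (0 genes each time, adjusted p of Tspan1 between 0.063 and 0.273). It was also lost in a fit of the 6 epithelial arrays alone, which share a slide (0 genes, 915 at an unadjusted p under 0.05).

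Of 25 gene lists fixed before the data were examined, 6 passed the set test in epithelium (camera with a preset correlation), none of them with an estimated correlation. Proliferation genes were higher in KO epithelium, with 21 of 22 measured members positive and a mean log2 fold change of 0.66 (camera adjusted p = 1.79e-05; adjusted p = 0.978 with an estimated correlation). Its mean was 0.37 without WT replicate 1 and 1.07 without WT replicate 3, whose own mean log2 ratio (-0.79) lay among those of the KO arrays (-1.12 to -0.70). None of the 22 passed on its own, whether over all genes or adjusted over the list alone. The mitotic kinase gene Aurka had 0.97 and the spindle gene Tpx2 1.15. Lists of other cell types were lower in KO epithelium. The endothelial list had a mean of -0.77 (adjusted p = 0.00035), with values of -1.62 for Robo4 and -1.90 for Esam. The fibroblast list had -0.59 (adjusted p = 0.0219), with -1.28 for Fap and -1.26 for Pdgfrb, measured above background on 2 of 3 KO arrays. The extracellular matrix list had -0.42 (adjusted p = 0.0211), with -1.12 for the elastin gene Eln. The adipocyte list had -0.81 (adjusted p = 0.0271), with -1.90 for the lipase gene Lpl (-0.46 with a second probe) and -1.54 for Pck1, and the erythroid list -0.96 (adjusted p = 0.0193), with -1.74 for the globin gene Hbb-bt and -0.83 for Alas2. Each of these 5 had an adjusted p of 0.978 with an estimated correlation, and no member passed, also when adjusted over the list alone. Without KO replicate 4 the fibroblast (-0.04), adipocyte (-0.36), matrix (-0.24) and erythroid (-0.66) calls ended (2 lists left). Without WT replicate 2 the same 4 calls ended, at -0.02, -0.18, -0.20 and -0.50, and in the deposited table they ended at -0.71, -0.85, -0.62 and -1.28. Without a filter on dim probes the adipocyte call ended (-0.71). The erythroid call also ended without KO replicate 3 (-0.62) or WT replicate 1 (-0.62), and its mean was -1.61 without KO replicate 1. Without WT replicate 3 the number of lists passing was 10, with means of -1.77 for the erythroid, -0.98 for the fibroblast and -0.70 for the matrix list, and without KO replicate 3 the fibroblast mean was -1.001. Luminal (0.42, adjusted p = 0.16), milk (-1.20, adjusted p = 0.0877) and retinoid genes (0.11, adjusted p = 0.794) were not called. Members with the smallest p were Prlr (1.70, and -0.29 with a second probe) and Foxa1 (1.97) among luminal genes, Wap (-3.30) among milk genes and the retinoic acid hydroxylase gene Cyp26b1 (2.11), and the basal keratin Krt17 had 1.79, the only member of the basal list called when adjusted over the list alone.

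The comparison of KO with WT stroma asked the same question of the tissue captured around the tumour cells. Across genes, WT stromal arrays correlated with WT epithelial arrays at a mean r of 0.81, and with each other at 0.82. For KO stroma with KO epithelium the mean r was 0.57. The differences below may therefore reflect epithelial content of the stromal samples, and an effect of Rarb on stromal cells was not tested apart from it. Here 468 genes were higher and 391 lower in KO (limma, 859 of 13275 genes at an adjusted p under 0.05). All 859 had non-overlapping groups, which their selection on the same arrays favours, so this adds no support. Of all genes 26.2% had such groups, against 10% by chance. Which direction held more genes depended on the setting, as 285 were higher and 349 lower with Agilent's processed signals. The transgene transcript Wnt1 was 11.6-fold lower in KO stroma, with log2 ratios of 3.24 ± 0.49 in KO and 6.77 ± 0.37 in WT (SD, n = 3 each; log2 fold change -3.53, SE 0.29, adjusted p = 0.000847), and -2.22 with a second probe. In WT stroma the Wnt1 ratio was 67.2% ± 4.32 of that in the same tumour's epithelium, and in KO stroma 6.60% ± 2.94 (SD, n = 3 tumours each). The second, dimmer Wnt1 probe gave 96.8% ± 16.8 and 48.9% ± 11.7, and it was above background on 0 of 3 KO stroma arrays. Its 48.9% is therefore an upper bound, and its -2.22 the least size of the fall. The largest falls were in Lao1 (67.6-fold), the milk protein genes Lalba (54.3-fold) and Wap (49.9-fold), Chil1 (17.7-fold), the transcription factor gene Foxi1 (13.8-fold), Clic6 (13.3-fold), the myoglobin gene Mb (13.2-fold), Itprid1 (12.8-fold) and Spns3 (12.5-fold), with adjusted p from 0.00395 to 0.0439. Of these Lao1 was above background on 1 of 3 KO arrays and Mb on 2. The largest rises were in Emilin2, which encodes a glycoprotein of elastic fibres (12.5-fold), Fstl1 (11.3-fold), the chemokine gene Ccl9 (11.2-fold), the folate receptor gene Folr2 (10.71-fold), the haem oxygenase gene Hmox1 (10.5-fold), the collagen gene Col5a3 (10.4-fold), Lrrc17 (9.95-fold), Cd248 (9.74-fold), Cd34 (9.71-fold) and Ptgis (9.33-fold), with adjusted p from 0.017 to 0.04. Second probes of Hmox1 and Cd34 gave smaller log2 fold changes of 0.13 and 1.19.

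**Figure D1:**
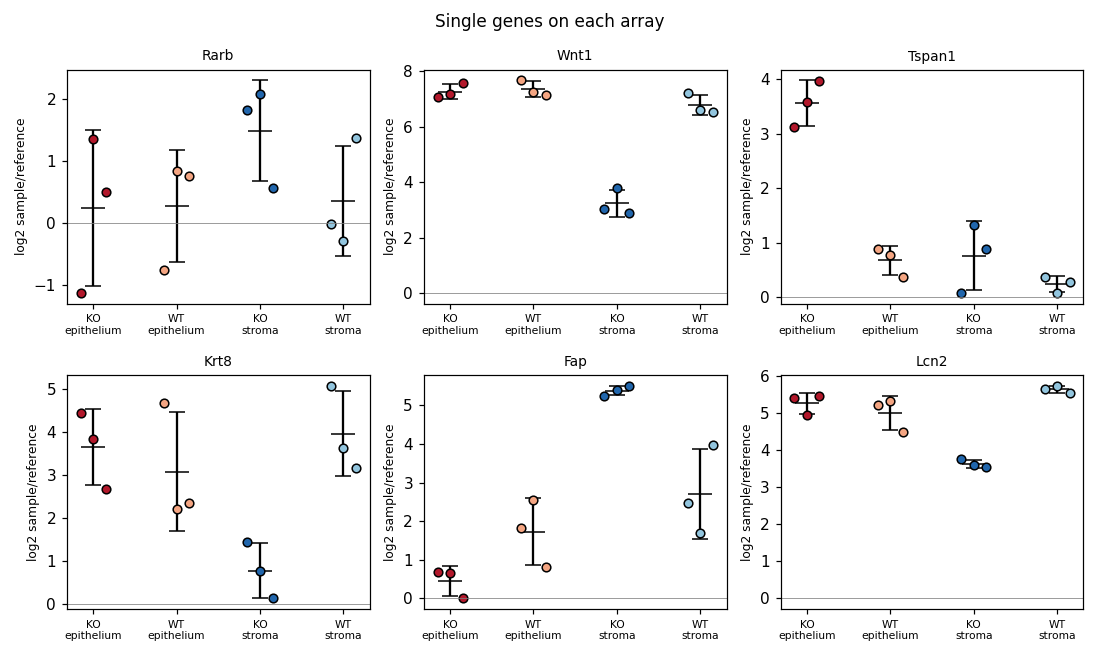
Log2 ratio of tumour sample over reference for 6 genes on each of the 12 arrays, by group. Points are arrays, and black bars give the mean and SD of 3 arrays. Wnt1 sits at 3.24 on average in KO stroma and between 6.77 and 7.35 in the other groups, and Rarb does not separate KO from WT.

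Epithelial lists were lower in KO stroma. Of 17 luminal genes 6 fell and none rose (9 adjusted over the list alone), with a mean of -1.30 (camera adjusted p = 2.1e-06; adjusted p = 0.263 with an estimated correlation). They included the keratin gene Krt8 (-3.18), the alveolar transcription factor gene Elf5 (-3.04), the tight junction gene Cldn3 (-2.34) and Spint1 (-1.94, and -0.77 with a second probe), which was above background on 2 of 3 KO arrays. Of 15 milk and secretory genes 4 fell and 1 rose (8 and 1 adjusted over the list alone), with a mean of -2.64 (adjusted p = 4.49e-05; adjusted p = 0.263 with an estimated correlation), among them Spp1 (-3.07, above background on 1 of 3 KO arrays) and Lcn2 (-2.01). The basal list had a mean of -0.85 (adjusted p = 0.0131; adjusted p = 0.496 with an estimated correlation) with no member past the threshold over all genes and 2 adjusted over the list alone. Among its members the calponin gene Cnn1 had -2.53, and the list was not called without KO replicate 1 (-0.58). Wnt pathway genes were lower as a list (-0.56, adjusted p = 0.0186; adjusted p = 0.263 with an estimated correlation), with 5 of 23 lower and 1 higher (6 and 2 adjusted over the list alone). Besides Wnt1 these were led by Rnf43 (-1.77), Myc (-1.59) and Sox9 (-1.57), which were above background on 2 and 1 of 3 KO arrays, and the call ended without KO replicate 3 (-0.49). Ribosomal protein genes had a mean of -0.60 (adjusted p = 6.76e-06; adjusted p = 0.496 with an estimated correlation) with 3 of 26 lower (5 adjusted over the list alone), Rps2 (-1.77), Rpl4 (-0.98) and Rps3 (-0.85).

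Lists of stromal cells and matrix were higher in KO stroma. All 22 fibroblast genes were positive and 4 rose over all genes (15 adjusted over the list alone), with a mean of 2.30 (camera adjusted p = 4.62e-10; adjusted p = 0.263 with an estimated correlation). They were Col5a1 (3.21), the fibroblast protease gene Fap (2.68), Col6a2 (2.24) and the growth factor receptor gene Pdgfra (1.49). Macrophage genes had a mean of 1.19 (adjusted p = 6.76e-06; adjusted p = 0.263 with an estimated correlation), where Fcer1g (2.20), the complement gene C1qc (1.96) and Aif1 (1.14) rose and Cd14 (-1.15) fell, out of 17 (11 higher and 1 lower adjusted over the list alone). The endothelial list had 1.26 (adjusted p = 2.18e-05; adjusted p = 0.263 with an estimated correlation) with none of 15 past the threshold over all genes and 8 adjusted over the list alone, where Pecam1 had 0.55 and Plvap 2.31. A second, dimmer Plvap probe gave -0.23. The matrix list had 1.27 (adjusted p = 6.76e-06; adjusted p = 0.263 with an estimated correlation), with 5 of 23 higher (8 adjusted over the list alone), including the basement membrane gene Nid1 (2.96), Timp1 (2.94) and Loxl1 (2.76). Second probes of Nid1 and Loxl1 gave 0.84 and 1.01. The epithelial-mesenchymal transition list had 1.16 (adjusted p = 0.000223; adjusted p = 0.263 with an estimated correlation). In it the intermediate filament gene Vim (2.92), the integrin gene Itga5 (1.30) and Prrx1 (1.20) rose and Wnt5b (-3.05) fell, out of 22 (10 higher and 1 lower adjusted over the list alone). Interferon response genes had 0.71 (adjusted p = 0.00341; adjusted p = 0.458 with an estimated correlation), with Gbp2 (0.94) the 1 of 17 that rose (4 adjusted over the list alone). Inflammatory mediators had 0.45 (adjusted p = 0.0315; adjusted p = 0.263 with an estimated correlation), with Ccl7 (1.72) and Csf1 (1.20) higher out of 13 (3 adjusted over the list alone). That call ended without KO replicate 1 (0.36), WT replicate 1 (0.26) or WT replicate 3 (0.36), and with Agilent's processed signals (0.73) or the filter on all 12 arrays (0.18), and the mean was 0.74 without WT replicate 2.

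The T and NK cell list was lower in KO stroma (-1.03, adjusted p = 0.0315; adjusted p = 0.662 with an estimated correlation) with none of 15 members past the threshold, also when adjusted over the list alone. Cd3g, above background on 1 of 3 KO arrays, had -1.57 and Nkg7 -0.89. This rested on WT replicate 2: without it the mean was 0.19, against -1.69 without WT replicate 1 and -1.59 without WT replicate 3, and the call also ended without KO replicate 1 (-0.83) or KO replicate 3 (-0.81). Agilent's processed signals (-1.29), the filter on all 12 arrays (-0.91) and array weights (-0.71) ended it too. Retinoid genes were not called as a list (0.29, adjusted p = 0.275), with 1 of 24 higher and 1 lower, although the retinoic acid binding protein gene Crabp2 fell (-2.41, SE 0.28, adjusted p = 0.00395). In the nerve and Schwann cell list, which was not called (0.16, adjusted p = 0.869), Sox10 (-2.10) fell and Pmp22 (2.27, and 0.55 with a second probe) rose. The number of genes depended on single arrays: it was 311 without KO replicate 1 (138 higher and 173 lower), 514 without KO replicate 3 (255 and 259), 174 without WT replicate 1 (70 higher and 104 lower) and 359 without WT replicate 2 (139 higher and 220 lower). In a fit of the 6 stromal arrays alone, which share a slide, 292 genes passed. Of 52 named genes called in stroma 16 stayed past the threshold whichever array was left out, Wnt1, Wnt5b, Elf5, Cldn3, Lcn2, Crabp2 and Sox10 among them. Itga5 was the only rise among the 16. The largest rises, from Emilin2 to Ptgis, each lost their call in 2 to 5 of the 6 fits. Of the largest falls Lao1 and Lalba lost theirs in 2 fits and Wap in 5.

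**Figure D2:**
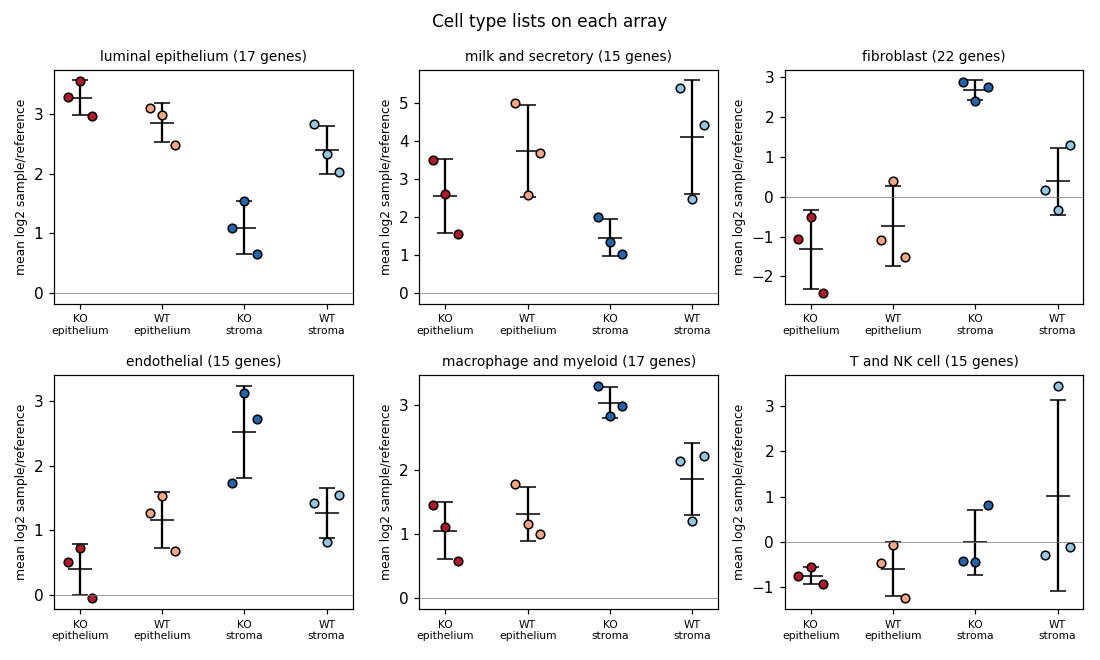
Mean log2 ratio of tumour sample over reference of 6 cell type lists on each of the 12 arrays, by group. Points are arrays, and black bars give the mean and SD of 3 arrays. Luminal genes average 1.10 in KO stroma and 2.39 in WT stroma, and fibroblast genes 2.68 and 0.38. One WT stroma array stands above the others of its group for T and NK cell genes.

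Stroma was compared with epithelium within each of the 6 tumours, which asked what the dissection separated. In stroma 1116 genes were higher and 889 lower (limma with tumour as a block, 2005 of 13275 genes). Of these 1167 had the same sign in all 6 tumours, as did 15.1% of all genes, against 3.125% by chance. The other called genes went the other way in at least 1 tumour. Among genes with the same sign in all 6 tumours, the largest rises were in the leukocyte gene Lsp1 (18.7-fold, log2 fold change 4.23, SE 0.34, adjusted p = 0.00326), C1qtnf3 (14.3-fold), the cartilage matrix gene Cilp (13.1-fold), the integrin genes Itgb7 (11.5-fold) and Itga11 (10.2-fold), Ctla2a (11.3-fold), the complement gene C2 (11.03-fold), the thrombomodulin gene Thbd (10.9-fold), Dok2 (10.8-fold) and S100a4 (10.6-fold). A second C1qtnf3 probe gave only 0.07. Above background were Cilp on 2 of 6 epithelial arrays, Thbd on 5 and C1qtnf3 on 5 in each compartment. The largest falls were in Crym (6.48-fold), the nucleoside transporter gene Slc28a3 (5.47-fold), the luminal transcription factor gene Foxa1 (5.41-fold), the laminin gene Lama1 (5.07-fold), the claudin genes Cldn8 (4.98-fold) and Cldn3 (4.83-fold), the prolactin receptor gene Prlr (4.98-fold), Wnt1 (4.92-fold), Rspo1 (4.79-fold) and Nat8 (4.76-fold). Crym was above background on 4 and Foxa1 on 1 of 6 stromal arrays, and second probes of Prlr and Wnt1 gave smaller log2 fold changes of -0.19 and -0.56. That Wnt1 probe was above background on 0 of 3 KO stroma arrays. Rarb was not called (log2 fold change 0.66, SE 0.42, adjusted p = 0.339).

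Of the 17 luminal genes 13 fell in stroma and none rose (15 adjusted over the list alone), with a mean of -1.31 (camera adjusted p = 8.3e-10; adjusted p = 0.0672 with an estimated correlation), Elf5 (-2.08) included. Of 18 basal genes 4 fell (5 lower and 1 higher adjusted over the list alone), including Col17a1 (-1.69) and Krt17 (-1.50), and the list had -0.49 (adjusted p = 0.0187; adjusted p = 0.572 with an estimated correlation), a call that ended without WT tumour 2 (-0.37), with Agilent's processed signals (-0.46), the filter on all 12 arrays (-0.50), quantile normalization (-0.39) or no tumour block (-0.49). Fibroblast genes had a mean of 2.56 with 16 of 22 higher (22 adjusted over the list alone; adjusted p = 5.07e-11, and adjusted p = 0.417 with an estimated correlation), led by the collagen genes Col1a1 (3.99), Col1a2 (3.94) and Col3a1 (3.83) and by Mfap5 (3.76). Macrophage genes had 1.26 with 13 of 17 higher and 1 lower (14 and 1 adjusted over the list alone; adjusted p = 1.66e-07, and adjusted p = 0.391 with an estimated correlation), among them the mannose receptor gene Mrc1 (2.26, above background on 5 of 6 epithelial arrays), Csf1r (2.23) and Fcer1g (2.08), while other probes of Csf1r gave 0.34 and 0.97. Endothelial genes had 1.12 with 7 of 15 higher (11 adjusted over the list alone; adjusted p = 3.35e-05, and adjusted p = 0.417 with an estimated correlation), Egfl7 (2.69) and Ramp2 (1.63) among them. The T and NK cell list had 1.17, and 0.70 without WT tumour 2 (adjusted p = 0.0022; adjusted p = 0.572 with an estimated correlation) with Cd4 (1.94, and 0.15 with a second probe) the 1 of 15 called (1 adjusted over the list alone), and the erythroid list 1.48 (adjusted p = 0.00688; adjusted p = 0.539 with an estimated correlation) with 3 of 8 higher (6 adjusted over the list alone), led by Hba-a1 (2.85).

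Matrix genes had a mean of 1.40 in stroma against epithelium with 11 of 23 higher (15 adjusted over the list alone; adjusted p = 1.66e-07, and adjusted p = 0.417 with an estimated correlation), including Timp1 (3.01) and Loxl2 (2.97, and 0.55 with a second probe). The transition list had 1.40 with 12 of 22 higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 1.24e-05, and adjusted p = 0.417 with an estimated correlation), led by the fibronectin gene Fn1 (4.46). Interferon response genes had 1.07 with 11 of 17 higher (13 adjusted over the list alone; adjusted p = 1.66e-07, and adjusted p = 0.391 with an estimated correlation), such as Oas1a (2.11) and Isg15 (1.70). Second probes of Oas1a and Isg15 gave 0.71 and 0.69. Inflammatory mediators had 1.24 with 5 of 13 higher (8 adjusted over the list alone; adjusted p = 3.38e-05, and adjusted p = 0.149 with an estimated correlation), with the chemokine genes Ccl2 (2.82) and Ccl7 (2.36), the latter above background on 1 of 6 epithelial arrays. Hypoxia and glycolysis genes had 0.74 with 4 of 18 higher (11 adjusted over the list alone; adjusted p = 0.000101, and adjusted p = 0.456 with an estimated correlation), with Pfkfb4 (2.24) and Adm (1.73, above background on 4 of 6 epithelial arrays). Proliferation genes had -0.38 (adjusted p = 0.0131; adjusted p = 0.612 with an estimated correlation) with none of 22 called, where Ccnb1 had -0.65 (-0.02 with a second probe) and Pcna -0.51, and that call ended without KO tumour 1 (-0.14), without WT tumour 3 (-0.23) or with array weights (-0.20). Retinoid genes were not called as a list (0.34, adjusted p = 0.219), with 3 of 24 higher and 2 lower, but the chemerin gene Rarres2 (3.86) and the retinaldehyde dehydrogenase gene Aldh1a2 (1.34) rose and Crabp2 (-1.32) fell. In the Wnt list, likewise not called (-0.12, adjusted p = 0.196), 5 of 23 were lower, Rnf43 (-1.61) with Wnt1 among them, and 2 were higher, Ccn5 (1.58) and Procr (1.51, above background on 4 of 6 epithelial arrays).

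Fits of the KO and of the WT tumours alone were chosen after the data had been seen. The fibroblast list averaged 4.01 in KO and 1.12 in WT tumours, and the luminal list -2.17 and -0.46. In the 3 KO tumours 1977 genes passed and in the 3 WT tumours 0 (limma, 1084 at an unadjusted p under 0.05). The difference between the genotypes was itself tested, as described next, and no gene passed there. In the WT tumours alone the endothelial (0.11), erythroid (0.51), basal and proliferation calls ended. All epithelial arrays lay on 1 slide and all stromal arrays on another, so slide and compartment cannot be told apart, and the reference channel, which holds the same RNA on every array, differed between the slides for 4090 of 11967 genes. The count was 1117 without KO tumour 1, 1107 without KO tumour 3, 930 without KO tumour 4, 1002 without WT tumour 1 and 1129 without WT tumour 3.

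Whether the KO effect itself differed between the compartments was tested within tumours. No gene passed (limma, 0 of 13275, with 2408 at an unadjusted p under 0.05), and the smallest adjusted p was 0.0539. Among genes with at least a 2-fold difference, the smallest p values included those of Wnt1 (-3.44), the luminal keratin gene Krt8 (-3.75), Clic6 (-3.49), Zfp750 (-2.80), Ripk4 (-2.45), the collagen gene Col4a6 (-2.45), Spns3 (-2.47), Aldoc (-2.36) and Tyro3 (-1.87). In each the KO effect was more negative in stroma, with an adjusted p of 0.0539. Other probes of Col4a6 and Tyro3 gave smaller differences between KO and WT stroma, with -0.10 for Col4a6. Rarb had 1.18 (adjusted p = 0.502). The count moved to 50 without the tumour block, to 269 with tumour as a random block and to 150 without WT tumour 3.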

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

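All tests of mixing were chosen after the result was seen, as was the expected overlap with the reference channel, while the other tests of that channel and those of other splits of the samples were written before. For 16 lists the KO effect differed between stroma and epithelium (camera on the difference within tumours, preset correlation), and none of them passed with an estimated correlation (smallest adjusted p = 0.0674). The mean difference of the KO effect, stroma minus epithelium on the log2 scale, was positive for fibroblast (2.89), endothelial (2.02), erythroid (1.93), extracellular matrix (1.69), macrophage (1.45), adipocyte (1.41), epithelial-mesenchymal transition (1.29), inflammatory mediators (0.65) and interferon response genes (0.62). It was negative for luminal (-1.72), milk (-1.44), basal (-0.75), immediate early and heat shock (-0.69), proliferation (-0.61), ribosomal protein (-0.59) and Wnt pathway genes (-0.56). Single tumours carried several of these calls. Without KO tumour 1 the basal (-0.70) and proliferation (-0.13) calls ended, and without KO tumour 3 the adipocyte (0.62), Wnt pathway (-0.34), basal (-0.61), interferon response (0.60) and immediate early (-0.54) calls. Without WT tumour 1 the proliferation (-0.33), interferon response (0.34) and Wnt pathway (-0.51) calls ended and the inflammatory mean was 0.39. Without WT tumour 3 the basal (-0.30), immediate early (-0.44) and Wnt pathway (-0.40) calls ended, and without WT tumour 2 the adipocyte mean was 0.86 and the transition mean 0.81.

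For the genes that differ between KO and WT stroma, the mean KO stroma was taken as WT stroma without epithelium, and each WT tumour's own epithelium was mixed in at the share given by Wnt1 (70.8%, 61.8% and 62.6% in WT tumours 1, 2 and 3). Under 50% of the difference was left for 96.7% of the 390 lower genes other than Wnt1 and 76.3% of the 468 higher genes, against at most 29.7% and 57.5% in 100 shuffles, and for 94.9% and 97.6% at the shares of the dimmer Wnt1 probe (118%, held to 100%, 87.0% and 77.0%). That probe was above background on 0 of 3 KO stroma arrays, and at 100% the mixture is the tumour's own epithelium. Its shares therefore add no separate support. Such a mixture cannot exceed the tumour's own epithelium, yet 82 of the lower genes averaged higher in WT stroma than in WT epithelium, 22 of them in all 3 tumours (limma, 0 past the threshold adjusted over these 390, 8 at an unadjusted p under 0.05), such as Spp1 (1.68 ± 1.22), Lalba (1.49 ± 1.75), Krt8 (0.88 ± 0.52), Lcn2 (0.63 ± 0.37) and Chil1 (0.57 ± 0.33; SD, n = 3 tumours). More tumour epithelium RNA in the WT stromal samples is a candidate explanation for most genes of both parts. It could not give levels above the epithelium, but no gene passed the test for such a level. The higher genes, with a median KO effect of 1.39, lay a median of 0.56 lower in WT stroma than in the mixture (-0.56). A slide row effect shared by both channels is argued against by the reference channel of the same arrays (0 called genes, 414 at an unadjusted p under 0.05, limma). That channel cannot show a row effect confined to the Cy3 samples. Whether the epithelial content reflects the cutting of the sections, tumour architecture that differs with Rarb, or both stays open. An effect of Rarb on stromal cells was not tested apart from the epithelial content.

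Other splits of the samples put these counts in context. The 6 stromal arrays can be split in 10 ways, too few for a share under 0.05; the real split gave 859 genes, 1 split gave as many, itself, and the highest other gave 0. For epithelium 3 of 10 splits gave at least the 1 gene of the real one and the highest other gave 2, and for the difference of the KO effect all 10 gave 0, again with too few splits. Between compartments 1 of 32 exchanges within tumours, the real one, gave 2005 genes and the highest other, with WT tumour 2 exchanged, 1219. This share met the bound of under 0.05 set beforehand. It is also the smallest that 32 exchanges can give, so it argues against chance without excluding it. With WT tumour 1 exchanged 690 genes passed, and with WT tumours 1 and 2 exchanged 400. With KO tumour 3, KO tumour 4 or WT tumour 3 exchanged alone 0 passed.

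The difference between compartments is confounded with the slide, and how much of it comes from the slide or its scan stays open. The reference channel, 1 RNA on all arrays, gave 4090 called genes of 11967 between the slides. Of the 1768 genes called between compartments and tested there, 593 were among them, where 604 would be expected without any association (Fisher's exact test for more than expected, p = 0.738). The number of reference calls met the bound set beforehand for a slide effect, which was too lenient, because a count does not say which genes. The reference differences were smaller, with an SD over genes of 0.25 on the log2 scale against 0.65 for the ratios, and 61 of them reached 2-fold. Within tumour epithelium the same channel called 50 genes between KO and WT arrays, which lie in different slide rows. Only genes with a reference signal well above background on at least 3 arrays were tested there. The reference signal of Tspan1 fell short of that, so this check does not cover it.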

How the results depend on the processing

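Scale and quantile normalization between arrays, probes without a symbol, and KO or WT tumours alone were chosen after seeing the data. For KO against WT epithelium 0 genes passed in place of 1 with Agilent's processed signals, Cy3 alone, the filter on all 12 arrays, quantile normalization, probes without a symbol, the 6 arrays alone or the deposited table, and 0 to 0 with a replicate left out. The 6 lists became 0 with an estimated correlation, 3 with the deposited table and 2 to 10 with a replicate left out. In stroma the 859 genes became 292 with the 6 arrays alone and 174 to 883 with a replicate left out, and the 13 lists 0 with an estimated correlation. The number in the title pairs no KO with WT tumours (deviations of same-numbered arrays correlated at 0.30 and -0.30 in epithelium and 0.04 and -0.06 in stroma). With it as a replicate block 0 genes and 3 lists passed in epithelium, and 2 genes and 16 lists in stroma. In that fit KO replicate 4 and WT replicate 2 have no partner of their number and add nothing to the comparison. Few degrees of freedom are left, so these counts do not show an effect of blocking. The 2005 genes between compartments became 3313 with Cy3 alone, where 45.5% were higher in place of 55.7%, 0 in WT tumours only and 930 to 1384 with a tumour left out, and the 13 lists 0 with an estimated correlation. The difference of the KO effect, 0 genes, became 55 without background subtraction, 112 with Cy3 alone, 29 without a filter on dim probes, 90 with the filter on all 12 arrays, 118 with scale and 135 with quantile normalization, 228 with array weights, 269 with a random block, 50 with no replicate block and 0 to 150 with a tumour left out. The cause was not tested. The deposited table was run in epithelium only. Aquantile leaves ratios as they are.

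Signs turned for Wnt1 in epithelium, to 0.23 with processed signals, 0.28 with scale, 0.20 with quantile normalization and 0.11 in the deposited table (-0.24 to 0.0698 with a replicate left out), and for Rarb in epithelium, to 0.0086 with Cy3 alone, 0.0018 with quantile normalization and 0.11 with the replicate block (-0.60 to 0.64 with a replicate left out). With that block, which compares replicates 1 and 3 only, the fibroblast and adipocyte lists in epithelium turned to 0.53 and 0.28. With a replicate left out Cd3g in stroma ran from -2.43 to 0.0212 and the T and NK cell list from -1.69 to 0.19. Of 1147 values of 58 named genes in stroma under 20 settings 265 lost their call, and of 1083 values of 52 genes between compartments 145 did. Signal over background limits the dim genes, as at most 46.3% of probes stood well above it on an array.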

Other observations

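The tests of lymphoid tissue and of basal genes were chosen after the values were seen, and the test of genes near Rarb was written before. In WT tumour 2 most lymphocyte genes were higher in stroma against epithelium than in any other tumour, the cytotoxic genes Gzma, Gzmb, Nkg7 and Prf1 excepted. The median difference between stroma and epithelium was 3.9996 on the log2 scale for 15 T and NK cell genes in that tumour, against -0.04 to 1.78 in the others, and its fibroblast genes were lower in stroma than in its own epithelium (-0.90). Among the brightest T and NK cell genes over both channels, Lck and Cd3e had 5.28 and 4.56 there, against at most 2.34 and 2.09 in the others. A candidate explanation is lymphoid tissue with both B and T cells in the captured region: the B cell and plasma cell list, 7 measured genes, had a median of 2.86 in this tumour and 0.11 to 0.88 in the others, with 3.98 for Pou2af1 and 4.30 for Cd79b. The plasma cell gene Jchain ran the other way, at -0.05 against 0.52 to 4.71 in the others. Infiltrating lymphocytes of both kinds would look alike.

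In the KO tumours the fall of epithelial genes from epithelium to stroma was uneven. Luminal genes had a median difference of -2.45 ± 0.19 and basal genes of -0.71 ± 0.30 (SD, n = 3 tumours), so that basal genes lay 1.74 ± 0.44 above luminal ones. An even loss of all epithelial cells would bring both down alike, but 5 contractile genes of the basal list are also expressed by smooth muscle of the stroma, and without them the gap was 1.42 ± 1.06. The bound of 2 SD chosen for this test was passed, and the reading as undecided was set afterwards because of the contractile genes. Krt5, chosen after its values were seen, showed -0.13 ± 0.10 with its bright probe and -0.67 ± 0.13 with a dimmer one, while Wnt1 showed -4.02 ± 0.65 in the same tumours.

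A knockout allele can bring variants of its donor strain along with the genes around it. Of 78 tested genes near Rarb on chromosome 14, 28 before it and 50 after it in gene order, 11 (14.1%) had an unadjusted p under 0.05 between KO and WT epithelium, against 8.03% of the other 13196 genes (Fisher's exact test, two-sided, p = 0.0585), and 25.6% against 21.5% between KO and WT stroma (p = 0.407). The bound set beforehand would have ruled the hypothesis out at any p of 0.05 or more, which was too strict, because a raised share that misses the threshold excludes nothing. The test is undecided.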
